A study of Mus musculus with 4 samples.

How the data were processed

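RNA from 4 lung samples of mice of the B6/J strain, as the labels give it, was measured on 1 single-colour Affymetrix array per sample. Of the samples, 2 were wild type and 2 carried a floxed allele of IKKα (IKKa floxed in the labels). All mice had received an adenovirus carrying Cre recombinase through the trachea, and the lungs were taken 4 months later, per the labels' protocols. Total RNA was extracted with Trizol and turned into biotinylated cRNA by a standard Affymetrix protocol, per the labels' protocols. Groups and replicate numbers were taken from the sample titles. The labels do not say whether each array stands for a separate animal, so p-values of single genes measure only the spread between these samples, which may be technical.

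The deposited table holds 1 linear intensity per probe set and array, not log transformed. The submitters' processing notes name Affymetrix Expression Console. Its version, and the algorithm that turned probe cells into a signal, are not given in the sources used here. With 2% of the probe sets trimmed from each end, the mean deposited intensity was 150.001 on every array, so the values had been scaled to a common trimmed mean before deposit. Their quantiles differed between arrays. Background correction and any handling of mismatch probes took place before the values used here, and no detection calls were used. Low intensities therefore have no stated floor, and no fold change is given as a bound.

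Probe sets were named through the platform annotation paired with the table. Of 45101 probe sets, 64 were array controls, 34958 had 1 gene symbol, 932 had several and 9160 were not listed. A probe set with several symbols or none named no gene. Symbols were updated through Entrez numbers against NCBI RefSeq (assembly GRCm38.p6), where 34754 probe sets matched and 0 symbols changed. That table was also used for chromosome membership and gene order. No genome build is named for the array values, so no coordinates are given. Chuk, the gene that encodes IKKα, is not analysed here. Each gene was represented by its probe set with the highest mean, which gave 18194 genes. Where probe sets of a gene chosen by the rule below and named in the text pointed in opposite directions, this is stated beside the gene, and probe sets that differed only in size are given for some genes.

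Intensities were transformed as log2(intensity + 16), so fold changes are on that scale and understate the change of low genes. The rule set before the data were examined called for quantile normalization only if array medians differed by over 0.1 on the log2 scale. The largest difference was 0.0646, and the deposited scaling was kept. Genes below the 30th percentile of mean level (intensity 20.4) were left out, and 12736 genes were tested. The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes without trend or robust options, two-sided, no covariates), with Benjamini-Hochberg adjustment and a threshold of 0.05. The design left 2 residual degrees of freedom per gene, to which eBayes added 4.78 prior degrees of freedom around a prior SD of 0.138. A single-gene exact permutation test of 2 against 2 cannot give a p below 0.333, so no such tests are given.

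Before the data were examined, 47 gene lists for cell types, neighbouring tissues and pathways were fixed, and 42 of them with at least 5 members tested were compared with all other genes by camera in limma, with a preset inter-gene correlation of 0.01. Another 4 lists were too small, and the list of sex-linked genes served only as a check. In all, 23 genes stood in more than 1 list. Camera with the preset correlation sets the members of a list against the other genes of the same arrays. Its p-values therefore measure a spread across genes and not the spread between samples, however small they are. Camera was run again with the correlation estimated from the residuals, and fry tested each list on its own. With an estimated correlation, camera rests on the 2 residual degrees of freedom, so a list can lose its call whatever its correlation. NF-κB target genes had an estimated correlation of -0.053, below the preset one, yet their camera p went from 2.16e-08 to 0.0262.

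The rule for named genes was also fixed in advance. It took the IKK genes, the 15 genes per direction with the largest log2 fold change among calls whose groups did not overlap, and up to 4 members of each described list by moderated t, with called members up to 8. Clone and model names were counted and not named, and sex-linked genes were given only in the check. Genes named outside the rule are marked where they appear.

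The procedure was tested on simulated data for this comparison, with 12736 genes, 2 against 2 arrays and 200 changed genes in each of 20 runs. It recovered 5.67% of genes changed 1.5-fold, 75.4% of those changed 2-fold and 98.4% of those changed 4-fold, and 4.96% of its calls were false. The simulated noise was normal, with variances drawn from the fitted prior, and did not depend on level. A false share near the threshold of 0.05 was therefore built in. It checks the procedure and does not measure the error rate of calls in the data. Shifted lists of 20 genes were called in 100% of cases and unshifted lists in 3%. These list calls used an unadjusted camera p under 0.05, and the simulated genes varied independently of each other. In the data, the estimated correlation was 0.760 for the called list of ribosomal proteins. The 3% therefore does not cover lists whose members vary together. Precision is limited by the number of arrays. The median residual SD on the log2 scale was 0.175 among the 3184 genes of lowest level and 0.0949 among the 3184 of highest level.

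The alternatives fixed in advance were the replicate number as a block, leaving out each array, no filter or a 50th percentile filter, the mean of all probe sets, leaving out probe sets marked as shared or cross-hybridising, quantile normalization, an intensity trend with a robust prior, and pseudocounts of 1 and 64. A test per probe set, an adjusted p of 0.1, a minimum of 2-fold, treat against a fold of 1.2, and 3 other list tests were also fixed. Leaving out genes of the X and Y chromosomes, and leaving out immunoglobulin, muscle and adipose genes, were added after seeing the data.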

Results

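Gene expression was profiled in mouse lung 4 months after intratracheal delivery of an adenovirus carrying Cre recombinase, the enzyme that excises DNA between loxP sites. IKKα is a kinase of the IκB kinase complex, which activates NF-κB transcription factors. The 2 wild type and 2 IKKa floxed lungs received the same virus, so the comparison asks how lungs with the floxed allele differed after exposure to Cre. Intensities reached 14417 to 19539 on the single arrays, with medians of 32.1 to 34.3. Across the genes tested, the wild type arrays correlated at r = 0.991, the floxed arrays at 0.987, and arrays of different groups at 0.972 to 0.976. These correlations are across genes, which are not independent replicates. The first principal component held 65.6% of the variance and separated the groups, and the second, with 20.4%, separated the floxed arrays from each other.

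The targeted gene, Chuk, is not analysed here, so the deletion was not checked at the level of its own transcript. The other subunits of the complex, the kinase IKKβ and the scaffold NEMO, did not pass the test. Ikbkb had a mean intensity of 492 ± 38.4 in wild type and 452 ± 5.0 in floxed lungs (SD, n = 2 each; log2 fold change -0.11 ± 0.12 SE, limma adjusted p = 0.740). Ikbkg gave 345 ± 26.4 and 292 ± 19.3 (SD, n = 2; -0.23 ± 0.13 SE, adjusted p = 0.489). Single probe sets of Ikbkb ranged from -0.41 to 0.48, and those of Ikbkg from -0.36 to 0.29. None of 13 tested members of the list of IKK and NF-κB subunits passed (median 0.00, camera adjusted p = 0.987).

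Sex-linked genes separated the groups without overlap. Xist, the RNA that silences an X chromosome in female cells, had an intensity of 27.4 ± 6.35 in wild type and 4438 ± 270 in floxed lungs (SD, n = 2; log2 fold change 6.69 ± 0.15 SE, adjusted p = 1.29e-05). The Y-linked genes Eif2s3y, Uty and Kdm5d fell in the floxed lungs, with log2 fold changes of -4.69, -3.38 and -3.03, to mean intensities of 4.96, 3.49 and 0.564, and the weakest of their other probe sets stood at -0.03, -0.11 and -0.03. Every difference between genotypes reported here is therefore also a difference between arrays with the male pattern and arrays with the female pattern. The arrays' 3′ to 5′ ratio of Gapdh, a measure of RNA integrity, was 1.18 and 1.10 in wild type and 1.44 and 1.68 in floxed lungs, while that of actin was 2.65 and 2.46 against 2.67 and 2.77.

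In the floxed lungs, genes of the interferon response, plasma cells, T cells and cytotoxic cells were higher as lists by camera with its preset correlation, the B cell list did not pass, and genes of cardiac muscle and of airway mucous secretions were lower. None of these list calls held with an estimated correlation (adjusted p = 0.422 to 0.485). That version rests on 2 residual degrees of freedom, so losing a call there does not show that correlated members made it. It does not exclude this either, as the estimated correlations of these lists were all above the preset 0.01. They were 0.214 for interferon response, 0.111 for plasma cells, 0.245 for T cells and 0.584 for cytotoxic cells. Cardiac muscle and mucous genes gave 0.469 and 0.433. Of 12736 genes tested, 220 passed the threshold, 127 higher and 93 lower, or 1.73% of genes. A change of at least 2-fold was seen for 148 of them, 80 higher and 68 lower. At an unadjusted p under 0.05 there were 1821 genes. The groups did not overlap for any of the 220, and they also did not overlap for 45.7% of all genes tested, against 33.3% by chance. The median log2 fold change of all genes was 3.2e-05. The count was 148 without wild type replicate 2, 248 without floxed replicate 2, 69 with no filter on low genes and 384 with an intensity trend and robust prior. Of 77 called genes that the rule for named genes selected, not all of them named in the text, 43 missed the threshold with no filter and 30 with a pseudocount of 1, while 53 passed whichever array was left out. Of the fixed gene lists, 19 of 42 passed camera, 14 higher and 5 lower. None of them passed with an estimated correlation, when 4 of the 42 had an unadjusted p under 0.05, and fry passed 1, with 14 at an unadjusted p under 0.05.

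**Figure D1:**
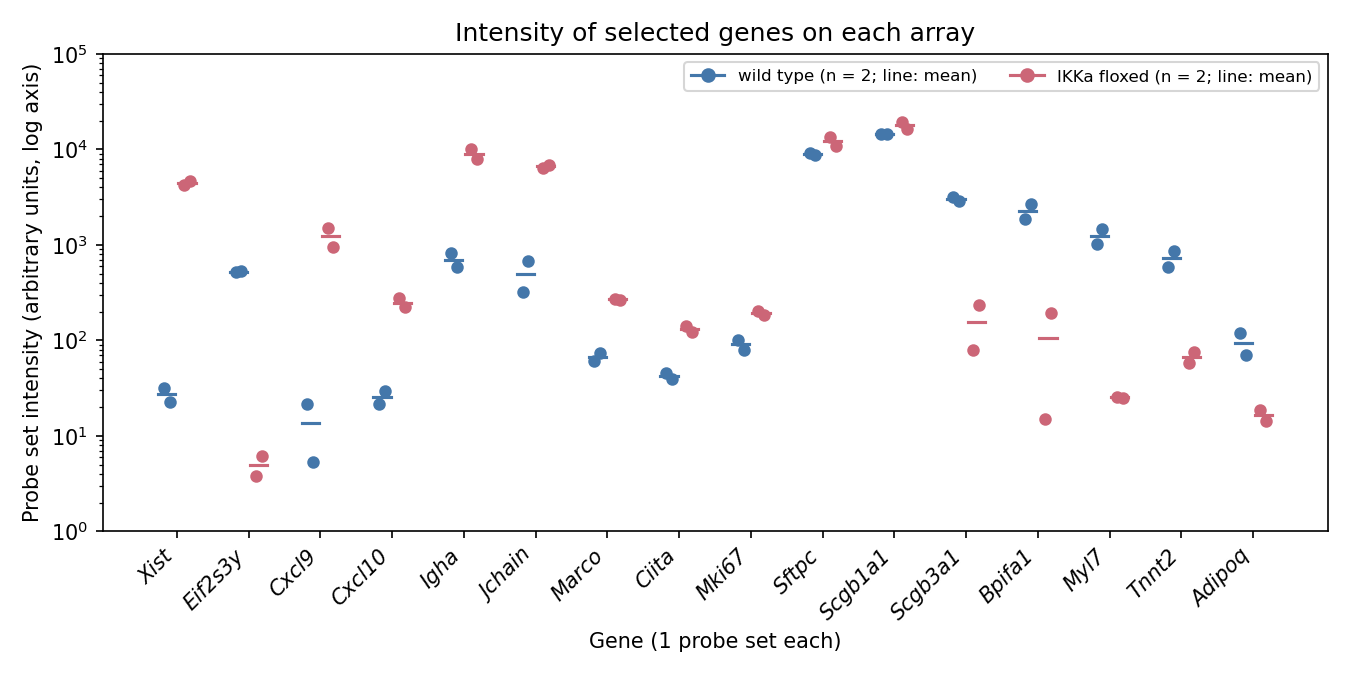
Probe set intensity (arbitrary units, log axis) of genes named in the text, with points for single arrays (wild type, n = 2; IKKa floxed, n = 2) and short lines for group means. Xist and Eif2s3y separate the groups in opposite directions, Cxcl9 rises from a mean of 13.5 to 1241, and Myl7 falls from 1251 to 25.3.

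Interferon response genes were the list with the most members past the threshold among those that rose. Cxcl9, a chemokine that attracts T cells through the receptor CXCR3, rose 43.2-fold, from 13.5 ± 11.6 to 1241 ± 397 (SD, n = 2; log2 fold change 5.43 ± 0.31 SE, limma adjusted p = 7.38e-04). Cxcl10, which acts on the same receptor, rose 6.37-fold (2.67 ± 0.16 SE, adjusted p = 0.00100). The interferon-inducible GTPases Gbp6, Iigp1 and Igtp rose by 2.47, 2.25 and 2.21 on the log2 scale. Ubd, a ubiquitin-like modifier, rose from 10.7 ± 4.68 to 247 ± 102 (SD, n = 2; 3.26 ± 0.27 SE, adjusted p = 0.00298). Zbp1, a sensor of nucleic acids, rose 3.11-fold, Gbp2 3.46-fold and Ifit1 2.36-fold. Calhm6 had a log2 fold change of 2.02 (adjusted p = 0.0186), and it, Ubd and Gbp6 stand in no fixed list. Of 24 interferon response genes tested, 12 rose and none fell, 22 rose when adjusted over the list alone, and all 24 lay above 0. The list's median log2 fold change was 0.78 (camera adjusted p = 3.49e-25), with adjusted p = 0.422 with an estimated correlation. Calhm6, Igtp and Ifit1 missed the threshold with no filter on low genes (adjusted p = 0.102, 0.0572 and 0.0567).

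Several immunoglobulin genes were higher in the floxed lungs. Igha, the constant region of IgA, went from 704 ± 156 to 9030 ± 1520 (SD, n = 2; log2 fold change 3.66 ± 0.19 SE, adjusted p = 5.35e-04), with its 3 probe sets between 3.61 and 3.82. Jchain, which joins IgA and IgM into polymers, went from 499 ± 246 to 6672 ± 286 (SD, n = 2; 3.79 ± 0.30 SE, adjusted p = 0.00259). Igkv8-30, Igkv9-120 and Igk, of the kappa light chain locus, rose by 4.76, 2.75 and 2.33 on the log2 scale, with the weakest probe sets of Igkv9-120 and Igk at 0.29 and 0.40. Ighm, the heavy chain of IgM, showed the largest log2 fold change outside the sex-linked genes, 6.29 ± 0.71 SE (adjusted p = 0.00960), but its wild type arrays stood at 25.4 and 230. Its 11 probe sets ran from -0.86 to 6.29, their mean gave 1.37 (adjusted p = 0.391), and its call was also lost with an intensity trend and robust prior (adjusted p = 0.251). Probes for immunoglobulin genes can bind transcripts of related segments, so the identity of each segment is uncertain. Mzb1, a chaperone of antibody secretion, rose 3.06-fold (1.61 ± 0.18 SE). Of 14 plasma cell genes, 4 rose and none fell, and 9 rose when adjusted over the list alone. Their median was 0.81 (camera adjusted p = 5.86e-11), with adjusted p = 0.422 with an estimated correlation. The B cell list did not pass with all arrays (median of 14 genes -0.12, camera adjusted p = 0.199), and its median ran from -0.18 without floxed replicate 1 (adjusted p = 0.0220) to 0.00 without floxed replicate 2 (adjusted p = 0.971). Blk and Ms4a1, both B cell genes, had log2 fold changes of -0.49 and -0.44 (adjusted p = 0.119 and 0.333).

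The T cell list was higher in the same lungs (median of 14 genes 0.73, camera adjusted p = 5.86e-11), a call lost with an estimated correlation (adjusted p = 0.422). Cd8b1, a chain of the CD8 co-receptor, rose 2.82-fold (log2 fold change 1.49 ± 0.21 SE, adjusted p = 0.0241) and Cd5 1.95-fold (0.96 ± 0.12 SE, adjusted p = 0.0153). Of the 14 genes, 4 rose and 10 did not pass, 12 rose when adjusted over the list alone, and all 14 lay above 0. Without wild type replicate 2, Cd5, Icos and Cd3g missed the threshold (adjusted p = 0.0679, 0.117 and 0.162), and of the 4 only Cd8b1 passed whichever array was left out. Among 15 genes of natural killer and cytotoxic cells, 3 rose, and 4 did when adjusted over the list alone (median 0.51, camera adjusted p = 5.57e-05, with adjusted p = 0.485 with an estimated correlation). Without floxed replicate 1 that median was 0.24, and without floxed replicate 2 it was 0.77 (camera adjusted p = 0.0279 and 6.29e-09). Ccl5, a chemokine made by cytotoxic lymphocytes, was 1 of the 3 and rose 4.10-fold (adjusted p = 0.0304), with adjusted p = 0.0831 under an intensity trend and robust prior. Nkg7, a granule protein, rose 2.34-fold (adjusted p = 0.0260), and Il2rb, a receptor chain for interleukin 2, 2.47-fold (adjusted p = 0.0304). Without floxed replicate 1 both missed the threshold (adjusted p = 0.0634 and 0.0800), as did Nkg7 without wild type replicate 2 and Il2rb without floxed replicate 2 or with the mean of its probe sets (0.134). Lists of neutrophils (6 genes, median -0.02, camera adjusted p = 0.987) and of mast cells, basophils and eosinophils (5 genes, median 0.18, camera adjusted p = 0.0694) did not pass with all arrays. The median of the mast cell, basophil and eosinophil list ran from 0.06 without wild type replicate 1 to 0.22 without wild type replicate 2. In that list, Prg2, the eosinophil major basic protein, rose from 5.94 ± 1.71 to 66.0 ± 10.4 (SD, n = 2; 1.90 ± 0.14 SE, adjusted p = 0.00218). Xist was 6.69 higher on the same arrays as these lymphocyte genes, and the Gapdh ratio was above 1.4 there.

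Genes of MHC class II antigen presentation and of monocytes were higher as lists, calls that an estimated correlation did not keep (adjusted p = 0.438 and 0.454). Ciita, the transactivator of MHC class II genes, rose 2.52-fold (log2 fold change 1.34 ± 0.13 SE, adjusted p = 0.00657), and Cd74, the invariant chain, rose 2.40-fold (1.26 ± 0.16 SE, adjusted p = 0.0145). H2-Ab1 went from 1837 ± 326 to 3801 ± 594 (SD, n = 2; 1.04 ± 0.17 SE, adjusted p = 0.0426, but 0.115 without wild type replicate 2 and above 0.05 without floxed replicate 1). Of 15 dendritic cell and MHC class II genes, 4 rose, 9 when adjusted over the list alone (median 0.55, camera adjusted p = 8.14e-09). The remaining one, H2-DMa (1.12 ± 0.20 SE, adjusted p = 0.0490), was lost without the same arrays as H2-Ab1 (adjusted p = 0.115 and 0.105). Of 16 genes of monocytes and interstitial macrophages, 3 rose and none fell, and over the list alone 9 rose and 2 fell (median 0.51, camera adjusted p = 4.28e-05). Fcgr4, an activating Fc receptor, rose 2.58-fold (1.37 ± 0.17 SE) and passed whichever array was left out. The other two, Fcgr1 and C1qb (1.04 and 0.89), each missed the threshold in 3 of the 4 fits with an array left out (adjusted p up to 0.0775 and 0.175), and both did so without wild type replicate 2. Alveolar macrophage genes moved both ways. Marco, a scavenger receptor, rose from 66.7 ± 9.07 to 271 ± 5.27 (SD, n = 2; 1.80 ± 0.13 SE, adjusted p = 0.00218), while Fabp4, a fatty acid binding protein of macrophages and adipocytes, fell by 1.13 ± 0.13 SE (adjusted p = 0.0114), on the same arrays as the adipose genes Car3, Adipoq and Retn (-4.14, -1.73 and -0.91). Mmp12, a matrix metalloproteinase, rose by 1.00 ± 0.14 SE (adjusted p = 0.0223) but missed the threshold without wild type replicate 2 (0.0758) or floxed replicate 1 (0.0535). Of 18 such genes 2 rose and 1 fell, with 6 and 2 over the list alone (median 0.18, camera adjusted p = 0.0179, 0.0524 without floxed replicate 2, 0.0711 by camera on ranks, and adjusted p = 0.438 with an estimated correlation).

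**Figure D2:**
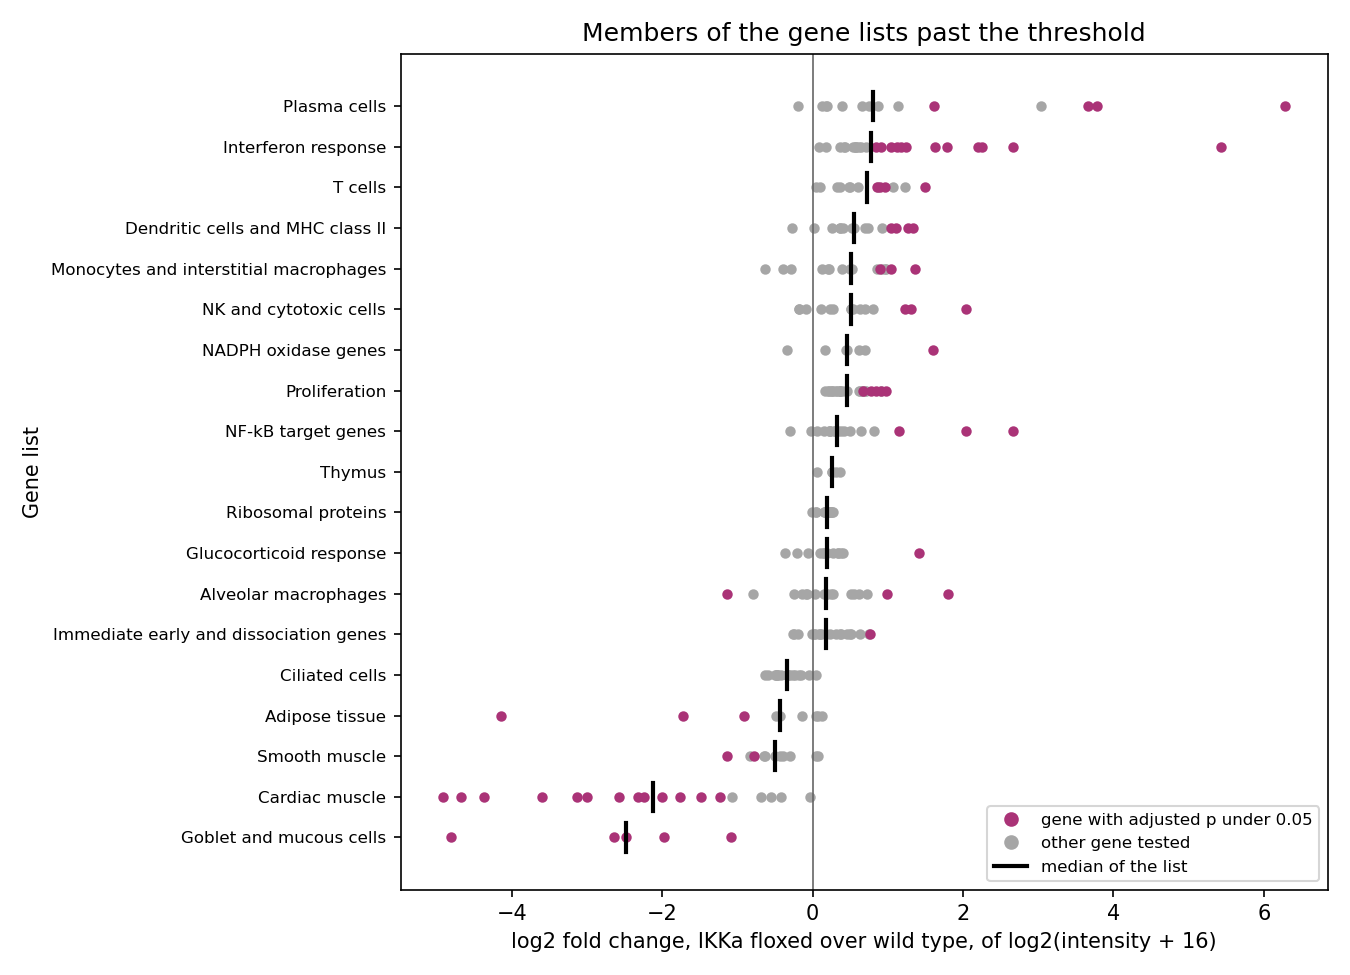
Log2 fold change (IKKa floxed over wild type, of log2(intensity + 16)) of every tested member of the 19 gene lists with a camera adjusted p under 0.05. Each point is 1 gene, purple points are genes with an adjusted p under 0.05, and black bars are list medians. Medians run from -2.48 for goblet and mucous genes to 0.81 for plasma cell genes, and that of ribosomal proteins (0.20) went to 0 after quantile normalization.

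NF-κB target genes were higher as a group. Of 18 tested, 3 rose and none fell, and 7 rose when adjusted over the list alone (median 0.32, camera adjusted p = 1.14e-07, with adjusted p = 0.422 with an estimated correlation). This was the 1 list that fry passed (adjusted p = 0.0169). The 3 were the chemokines Cxcl10, Ccl5 and Ccl20, and Cxcl10 and Ccl5 also stand in other lists. Ccl20 rose 2.22-fold (1.15 ± 0.20 SE, adjusted p = 0.0484, 0.103 without wild type replicate 2, and above 0.05 without either floxed array). The list of lymphoid chemokines and non-canonical NF-κB targets did not pass (7 genes, median 0.23, camera adjusted p = 0.0693), though it did without wild type replicate 2 (median 0.24, adjusted p = 0.0298) and after quantile normalization (adjusted p = 0.0485), with an intensity trend and robust prior (0.0499) or with a pseudocount of 64 (0.0440). Cybb, the catalytic subunit of the phagocyte NADPH oxidase, lies on the X chromosome and rose from 500 ± 56.2 to 1555 ± 213 (SD, n = 2; log2 fold change 1.61 ± 0.15 SE, adjusted p = 0.00548). Its partner Cyba stood at 0.62 ± 0.13 SE (adjusted p = 0.0894). Of 7 NADPH oxidase genes 1 rose, and over the list alone 5 rose and 1 fell (median 0.46, camera adjusted p = 0.00158, with adjusted p = 0.454 with an estimated correlation). NRF2 target and glutathione genes did not pass as a list (23 genes, median -0.04, camera adjusted p = 0.152), with adjusted p = 0.0464 without floxed replicate 1 (median -0.15), 0.0357 with the mean of all probe sets and 0.0160 after quantile normalization. Aldh3a1, an aldehyde dehydrogenase, was the 1 member that fell (-0.73 ± 0.13 SE, adjusted p = 0.0470), and it missed the threshold whichever array was left out (adjusted p up to 0.184).

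Proliferation genes were higher as a list. Of 25 tested, 5 rose, 12 when adjusted over the list alone, and all 25 lay above 0 (median 0.45, camera adjusted p = 1.16e-14, with adjusted p = 0.422 with an estimated correlation). Mki67, the Ki-67 antigen of cycling cells, went from 91.0 ± 15.6 to 194 ± 11.6 (SD, n = 2; log2 fold change 0.98 ± 0.14 SE, adjusted p = 0.0266). Ube2c, Rrm2, Mcm5 and Nusap1 had log2 fold changes of 0.91, 0.85, 0.78 and 0.67. Of the 3 probe sets of Mcm5, 1 stood at -0.01, and their mean gave 0.43 (adjusted p = 0.173). None of the 5 held without wild type replicate 2, when Mki67 had an adjusted p of 0.0973 and Nusap1 of 0.229, and each was also lost without at least 1 other array. Cdkn1a, an inhibitor of cyclin-dependent kinases, rose from 218 ± 0.126 to 612 ± 125 (SD, n = 2; 1.41 ± 0.16 SE, adjusted p = 0.00960) and was the 1 gene of 14 in the p53 and senescence list that passed (list median 0.03, camera adjusted p = 0.246). None of 15 genes of the list for lung tumours and epithelial progenitors passed over all genes (median 0.00, camera adjusted p = 0.868), and 1 fell when adjusted over the list alone. Sox2, a transcription factor of airway epithelium, stood at -0.57 ± 0.12 SE in that list (adjusted p = 0.0923).

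Secretory genes of the airways were among those that fell most. Bpifa1, an airway surface protein, went from 2294 ± 588 to 105 ± 128 (SD, n = 2; log2 fold change -4.81 ± 0.77 SE, adjusted p = 0.0373), with floxed arrays at 14.99 and 195. Scgb3a1, a secretoglobin, went from 3032 ± 178 to 158 ± 110 (SD, n = 2; -4.29 ± 0.40 SE, adjusted p = 0.00519). With an intensity trend and robust prior, neither passed (adjusted p = 0.351 and 0.123). Reg3g, an antibacterial lectin, had a log2 fold change of -3.59, Bpifb1 of -2.64, the gel-forming mucin Muc5b of -2.48 and the trefoil factor Tff2 of -1.98. Bpifa1, Muc5b and Tff2 missed the threshold with no filter on low genes (adjusted p = 0.156, 0.119 and 0.0685). Of 11 goblet and mucous genes with a value, 5 passed the filter on low genes, and the others were not tested. The filter used the mean level, so a gene low in floxed lungs could pass through its wild type arrays. For Muc5b the wild type arrays stood at 110 and 163, and the floxed arrays at 2.07 and 24.2. All 5 goblet and mucous genes tested fell, over all genes and when adjusted over the list alone (median -2.48, camera adjusted p = 8.21e-09, with adjusted p = 0.422 with an estimated correlation). Among them Ltf, which encodes lactoferrin, stood at -1.08 ± 0.18 SE (adjusted p = 0.0448), and it missed the threshold without wild type replicate 1 or either floxed array (adjusted p up to 0.0930), with no filter on low genes (0.156) and after quantile normalization (0.0586). Ciliated cell genes moved less. None of 18 passed over all genes, 8 fell when adjusted over the list alone, and 17 lay below 0 (median -0.34, camera adjusted p = 3.30e-07, with adjusted p = 0.451 with an estimated correlation). Mlf1 stood at -0.64 ± 0.14 SE and Ccdc113 at -0.48 ± 0.12 SE (adjusted p = 0.0908 and 0.142). Xist and the Gapdh ratio separated the same arrays, at 6.69 on the log2 scale for Xist and at 1.10 to 1.18 against 1.44 to 1.68 for the ratio.

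The list of club cells, the main secretory cells of small airways, did not pass with the values as deposited (12 genes, median -0.21, camera adjusted p = 0.0807). It passed after quantile normalization (median -0.28, adjusted p = 2.63e-04), and without floxed replicate 1 (-0.37, adjusted p = 0.00424), wild type replicate 2 (-0.19, adjusted p = 0.0273) or wild type replicate 1 (-0.17, adjusted p = 0.0479), while its median was -0.08 without floxed replicate 2 (adjusted p = 0.410). It also passed with an intensity trend and robust prior (0.0499) and a pseudocount of 64 (0.0440). Scgb3a1 was its 1 member past the threshold, and 2 fell when adjusted over the list alone. Scgb1a1, a secretoglobin abundant in club cells and named after its values were seen, stood at 14484 ± 95.6 and 17871 ± 2359 (SD, n = 2; log2 fold change 0.30 ± 0.14 SE, adjusted p = 0.399). These values lie close to the highest intensities of the arrays (14417 to 19539), and whether the probe set could still show a change there was not tested. The gas-exchange epithelium did not pass either. Genes of type 2 cells, which make surfactant, had a median of 0.12 (14 genes, camera adjusted p = 0.0807, 0.0296 with an intensity trend and robust prior, 0.0440 with a pseudocount of 64 and 0.0469 by camera on ranks). In it, Sftpc stood at 0.44 ± 0.15 SE (adjusted p = 0.246), and its other probe set at -0.29. Type 1 cell genes had a median of 0.07 (12 genes, camera adjusted p = 0.609), with Pdpn, the 1 gene that fell when adjusted over the list alone, at -0.69 ± 0.13 SE (adjusted p = 0.0518) and Ager at 0.23 ± 0.12 SE (adjusted p = 0.451). Endothelial genes had a median of 0.08 (18 genes, camera adjusted p = 0.311), which ran from -0.03 without wild type replicate 1 to 0.17 without wild type replicate 2. Mesothelial genes had a median of -0.08 (10 genes, camera adjusted p = 0.609), and their direction turned with the array left out. The median was -0.55 without floxed replicate 2 (adjusted p = 0.00411) and -0.42 without wild type replicate 1 (0.0172), but 0.37 without floxed replicate 1 (0.0947) and 0.30 without wild type replicate 2 (0.250). The list of basal and squamous epithelium was too small to test, with a median of 0.04 over 3 genes.

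Cardiac muscle genes showed the lowest camera p of all lists with the preset correlation and all arrays. With an estimated correlation, their unadjusted camera p was 0.0586, against 0.0262 for NF-κB target genes. The atrial light chains Myl7 and Myl4 fell 30.2-fold and 12.1-fold. For Myl7 this was from 1251 ± 316 to 25.3 ± 0.447 (SD, n = 2; log2 fold change -4.92 ± 0.18 SE, adjusted p = 1.16e-04), and for Myl4 a second probe set stood at 0.09. Log2 fold changes were -4.68 ± 0.35 SE for Myh6, the alpha heavy chain of cardiac myosin, -4.36 ± 0.20 SE for Sln, a regulator of the calcium pump, and -3.13 and -2.99 for the troponins Tnnt2 and Tnni3. Outside the list, they were -4.65 for Mb, which encodes myoglobin, -2.96 for Smpx and -2.75 for the mitochondrial creatine kinase Ckmt2. The weakest probe sets of Myh6, Sln, Tnnt2 and Mb stood at -0.20, -0.49, -0.07 and -0.01. Of 18 cardiac genes 13 fell and none rose, 16 fell when adjusted over the list alone, and all 18 lay below 0 (median -2.12, camera adjusted p = 4.88e-26, with adjusted p = 0.422 with an estimated correlation). Smim6 also fell (-3.16 ± 0.17 SE, adjusted p = 5.45e-04). The skeletal muscle list was too small to test. The median of its 3 genes was -0.32, and Ckm fell by 1.23 on the log2 scale (adjusted p = 0.0473, 0.0789 without wild type replicate 2), while its other probe set stood at -0.18. Xist, at 6.69, and the Gapdh ratio separated these same arrays.

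Smooth muscle and adipose genes were lower as lists. Of 11 smooth muscle genes 2 fell, 8 when adjusted over the list alone (median -0.49, camera adjusted p = 2.23e-06, with adjusted p = 0.438 with an estimated correlation). The 2 were Acta2 and Myh11 (-0.78 ± 0.12 SE and -1.14 ± 0.20 SE, adjusted p = 0.0307 and 0.0473). Without wild type replicate 2 their adjusted p was 0.146 and 0.101, both were also above 0.05 without either floxed array, and Acta2 without any 1 array. The 3 probe sets of Acta2 ran from -0.78 to 0.02, and their mean gave -0.25 (adjusted p = 0.405). Car3, a carbonic anhydrase abundant in fat and slow muscle, had a log2 fold change of -4.14 ± 0.30 SE (adjusted p = 0.00218), with the weakest of its 4 probe sets at -0.36, and Adipoq, the hormone adiponectin, of -1.73 ± 0.22 SE (adjusted p = 0.0145). Retn, which encodes resistin, stood at -0.91 ± 0.14 SE (adjusted p = 0.0277), with its call lost without wild type replicate 1 or either floxed array (adjusted p up to 0.0975). Of 9 adipose genes 3 fell, 4 when adjusted over the list alone (median -0.44, camera adjusted p = 3.59e-04, with adjusted p = 0.438 with an estimated correlation), and without wild type replicate 1 their median was -0.24 (camera adjusted p = 0.00128). The fibroblast and matrix list did not pass (20 genes, median 0.01, camera adjusted p = 0.868). In it the matrix glycoprotein Mfap4 rose 3.15-fold (1.66 ± 0.18 SE, adjusted p = 0.00923) and the proteoglycan Dcn fell by 1.40 ± 0.12 SE (adjusted p = 0.00360). The other probe set of Dcn stood at 0.01, and the mean of both gave -0.70 (adjusted p = 0.108).

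Pik3ap1, an adaptor of PI3-kinase signalling in B cells and myeloid cells, rose 5.01-fold, from 74.5 ± 18.9 to 434 ± 48.2 (SD, n = 2; log2 fold change 2.32 ± 0.17 SE, adjusted p = 0.00218), while its other probe set stood at -0.59. Probe sequences were not used here, so a difference seen at 1 probe set alone was not told apart from a sequence difference under its probes. Among 16 tested neighbours of Chuk on chromosome 19, Hps1 fell by 1.27 ± 0.13 SE (adjusted p = 0.00672) and none rose, while 1 fell and 1 rose when adjusted over the list alone. Of the 4 probe sets of Hps1, 1 stood at 0.65, and their mean gave -0.30 (adjusted p = 0.309). The median of that list was 0.03 and its mean -0.07, while camera pointed down (adjusted p = 0.987). Of 7 genes known to vary between mouse strains, Wdfy1 rose 2.42-fold (1.27 ± 0.13 SE, adjusted p = 0.00674), with all 5 probe sets above 0. Nnt, in the same list, stood at 0.85 ± 0.19 SE (adjusted p = 0.0978) and also rose when adjusted over the list alone, and its 3 probe sets ran from -0.16 to 1.08. The strain list's median was -0.08 and its mean 0.22, and camera pointed up (adjusted p = 0.392).

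Lists that reflect handling and general physiology had medians of at most 0.26. Immediate early genes, which respond within minutes to stimulation or tissue handling, had a median of 0.18 (21 genes, camera adjusted p = 0.00111, with adjusted p = 0.438 with an estimated correlation), or 0.30 without wild type replicate 1 (camera adjusted p = 2.02e-04). Egr1 was the 1 that rose (0.76 ± 0.12 SE, adjusted p = 0.0364), with 6 over the list alone, and it missed the threshold whichever array was left out (adjusted p up to 0.157). Glucocorticoid response genes had a median of 0.19 (13 genes, 1 rose, also adjusted over the list alone, camera adjusted p = 0.0137, with adjusted p = 0.438 with an estimated correlation). The 1 was Cdkn1a, and the list missed the threshold without floxed replicate 2 (0.12, adjusted p = 0.177), with the mean of all probe sets (0.0825) and after quantile normalization (0.0790). None of 17 ribosomal protein genes passed, and their median of 0.20 (camera adjusted p = 0.00205, with adjusted p = 0.635 with an estimated correlation) went to 0 after quantile normalization, with the test pointing down (adjusted p = 0.860). The ribosomal list also missed the threshold without wild type replicate 2 (median 0.15) or floxed replicate 1 (median 0.10). None of 5 thymus genes passed (median 0.26, camera adjusted p = 0.0363, with adjusted p = 0.438 with an estimated correlation), and the list was lost without floxed replicate 2 (0.09, adjusted p = 0.271), wild type replicate 1 (adjusted p = 0.0850) or wild type replicate 2 (0.0837), and its median was 0.43 without floxed replicate 1. It was also lost with no filter on low genes (0.259), with an intensity trend and robust prior (0.0775) and with a pseudocount of 64 (0.0709).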

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

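The comparison in this part was chosen after the gene-level result was seen. Among the 9160 probe sets that the annotation used here does not pair with a gene, 3374 lay above the same level as the genes tested and were compared in the same way. Of these, 28 passed the limma threshold, 16 higher and 12 lower in the floxed lungs, and 297 had an unadjusted p under 0.05. They stood out because they carry a signal in data that the gene-level comparison does not use. Among those higher, the largest log2 fold changes were 5.43 ± 0.76 SE, from intensities of 152 ± 188 to 4655 ± 2176 (SD, n = 2), and 4.22 ± 0.58 SE (adjusted p = 0.00828 for both). Among those lower, they were -5.63 ± 0.22 SE, from 1012 ± 23.5 to 5.08 ± 5.5 (SD, n = 2), and -5.19 ± 0.18 SE (adjusted p = 3.55e-07 and 2.84e-07). No explanation was tested for these probe sets. They were compared between the same arrays that the sex-linked genes separate, so sex cannot be told apart from genotype here either. Of the 5 sex-linked genes fixed for the check, 4 had a value. Ddx3y, on the Y chromosome, had none, so probe sets that measure it may be among those that fell.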

How the results depend on the processing

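Leaving out X and Y genes, and leaving out immunoglobulin, muscle and adipose genes, were chosen after seeing the data. The 220 genes past the threshold became 69 with no filter on low genes, 104 with a pseudocount of 1, 359 with a pseudocount of 64, 384 with an intensity trend and robust prior, 389 at an adjusted p of 0.1 and 117 with treat against a fold of 1.2. The last 2 follow from the wider threshold and the fold minimum, and for the others the cause was not tested. Leaving out 1 array at a time gave 148 to 248 genes, with 44.8% of the calls higher without floxed replicate 1 against 57.7% with all arrays, and the lone array left in a group was assumed to vary like the other group. After quantile normalization 65.5% of 229 calls were higher. The replicate numbers gave no sign of pairing, as deviations of same-numbered arrays from their group means correlated at -0.00029 across genes. With 2 arrays per group this cannot exclude pairing. With the number as a block 188 genes passed, of which 170 were among the 220, and again 19 lists. Without X and Y genes 211 passed, and without immunoglobulin, muscle and adipose genes 187. The 19 gene lists became 0 with an estimated correlation and 1 with fry, and 17 to 21 when 1 array was left out. The ribosomal protein list turned its direction under quantile normalization, where its median was 0 (adjusted p = 0.860). Of 77 called genes that the rule selected, none changed sign under these settings. With all arrays, 31 kept their call in every setting in which they were tested. Some settings left genes out, and with the 50th percentile filter 51 of the 77 were tested. Of those calls, 43 were lost with no filter on low genes, 30 with a pseudocount of 1, 13 with the mean of all probe sets and 10 with the block. Of genes chosen after their values were seen, Zfp991 changed sign with the mean of its probe sets (-0.23, adjusted p = 0.496; the cause was not tested). The alternatives for Chuk were not run, since it is not analysed here. No detection calls were used, so signal over background was not assessed, and low genes are the least certain.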

Other observations

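Among the tests in this part, those on sex, on lymph node tissue, on other splits of the arrays and on windows away from Chuk were chosen after the result was seen, as were the genes named in this paragraph, Cep55 and Cytl1. Several genes of MHC class I antigen presentation were higher in the floxed lungs, as values with no test of a group. Nlrc5, the transactivator of class I genes, rose 3.22-fold, from 115 ± 3.38 to 408 ± 53.7 (SD, n = 2; log2 fold change 1.69 ± 0.14 SE, limma adjusted p = 0.00279). The peptide transporter Tap1 rose 3.21-fold (1.68 ± 0.13 SE), and the immunoproteasome subunits Psmb9 and Psmb8 rose by 1.46 and 1.39. Tap1 missed the threshold with the mean of its probe sets, and Psmb8, Slpi and F13a1 with no filter on low genes. Cd274, the checkpoint ligand PD-L1, rose 3.29-fold (1.72 ± 0.14 SE, adjusted p = 0.00302), Cxcl11, the remaining CXCR3 ligand, 3.44-fold, and the GTPase Irgm1 2.85-fold. Slpi, an inhibitor of neutrophil proteases, rose 2.97-fold, while F13a1, a coagulation factor subunit made by macrophages, fell by 1.16 ± 0.13 SE (adjusted p = 0.00847).

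None of the lists in this paragraph, on metabolism, stress, the circadian clock and type 2 immunity, passed camera with all arrays. Medians were 0.06 for oxidative phosphorylation (22 genes, adjusted p = 0.392), 0.02 for hypoxia and glycolysis (16 genes, adjusted p = 0.641), -0.07 for cholesterol and fatty acid synthesis (18 genes, adjusted p = 0.199) and 0.08 for heat shock and the unfolded protein response (18 genes, adjusted p = 0.0754). The last passed with an intensity trend and robust prior (0.0345) or a pseudocount of 64 (0.0440), and 1 of its genes rose when adjusted over the list alone. The oxidative phosphorylation median ran from -0.04 without floxed replicate 1 to 0.13 without floxed replicate 2. The clock genes had a median of 0.05 and a mean of -0.02, with camera pointing down (17 genes, adjusted p = 0.987). For xenobiotic metabolism the median was 0.00 (14 genes, adjusted p = 0.694), and Sult1d1, a sulfotransferase, fell by 1.03 ± 0.17 SE (adjusted p = 0.0387, 0.111 without wild type replicate 2 and above 0.05 without floxed replicate 2). Genes of type 2 immunity had a median of 0.10 (6 genes, adjusted p = 0.609), of which 2 rose and 1 fell when adjusted over the list alone. The lists of red blood cells (4 genes, median -0.20) and of thyroid, liver and other neighbouring tissue (1 gene, Alb, at -0.24) were too small to test.

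Cardiac muscle, mucous and ciliated cell genes were lower as lists in the floxed lungs, though no ciliated cell gene passed singly. The 3 list calls were lost with an estimated correlation (adjusted p = 0.422, 0.422 and 0.451). Scaling between arrays is argued against, since the cardiac list's median was still -2.095 after quantile normalization and the 3 lists still passed. A candidate explanation is that less tissue of the lung root, where large airways and heart-like muscle of the pulmonary veins lie, entered the floxed samples. For cartilage and Schwann cell genes of that region, the mean log2 fold change was -0.13 (95% interval across 9 genes -0.361 to 0.102). The interval reaches both 0 and the ciliated median of -0.34 and does not measure the spread between samples, so this stays open. The parts differed, with both cartilage genes below 0 (median -0.40) and a median of 0.02 for the 7 Schwann cell genes. Of the cartilage genes, Cytl1 fell by 0.76 ± 0.12 SE (adjusted p = 0.0364, above 0.05 whichever array was left out), and 2 genes are too few to decide. Sex cannot be told apart from genotype for this pattern, because Xist (6.69) separates the groups completely. An effect of the floxed allele also stays open, and these values do not rank the explanations.

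Interferon response, T cell, plasma cell and MHC class II genes were higher as lists in the floxed lungs, and these 4 list calls were lost with an estimated correlation (adjusted p = 0.422 to 0.438). Scaling between arrays is argued against, as the interferon median stayed at 0.7748 after quantile normalization with all 4 lists past the threshold. Lymph node tissue is argued against, because B cell genes had a mean of -0.109, below the T cell median of 0.728. The 95% interval (-0.237 to 0.0184) is across 14 genes of the same arrays and does not measure the spread between samples. With 1 array left out, the B cell median was at most 0.001 (without floxed replicate 2). The T cell median was then at least 0.63 (without wild type replicate 2). Dosage of X-linked genes stays open for this pattern, because 0 tested members of the 4 lists lie on the X chromosome, which set the share among the 24 called members at 0% beforehand, and an X-linked regulator of other genes was not tested. Over all genes, 4 of the 127 called higher lay on the X chromosome, where 3.12% of the genes tested lie (one-sided Fisher's exact p = 0.564), so no excess of X-linked genes was detected among the calls. Thymus tissue stays open, since Rag1, Dntt and Ptcra, at low intensity on all arrays, had a mean of -0.0614 (95% interval across these genes -0.739 to 0.616). Sex (Xist 6.69) and the floxed allele itself may each lie behind this pattern, and these 4 arrays cannot separate them.

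Pik3ap1 lies on chromosome 19 near Chuk, and a candidate explanation for its rise is DNA of another strain carried along with the floxed allele. Its other probe set stood at -0.59, and whether the 5.01-fold value is a change in transcript level or a sequence difference under the probes was not tested. Of the 100 tested genes nearest to Chuk in gene order, 3 passed the threshold (Cep55, Pik3ap1 and Hps1), against 1 in the median window of that size, and 22.1% of windows held as many, so this cannot be told apart from the usual clustering of calls, and Cep55 missed the threshold without wild type replicate 2 (adjusted p = 0.146) or either floxed array. Fuller windows of that size lay elsewhere, with 12 calls on chromosome 17, among MHC genes, 8 on chromosome 5, 8 in another part of chromosome 19, and 7 each on chromosomes 4 and 11.

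With 4 arrays there are 3 ways to split them into 2 and 2, too few for a share under 0.05. The split by genotype gave 220 genes, the most that any other split gave was 0 (272 genes at an unadjusted p under 0.05 with limma in each), and 1 of the 3 splits, the real one itself, gave that many. The other splits put 1 wild type and 1 floxed array in each group, so the difference between genotypes counted there as spread within groups. Their 0 calls are therefore no measure of how many genes an arbitrary grouping would give.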
